A study of Mus musculus with 6 samples.

How the data were processed

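Total RNA of renal cortex was taken from 6 mice, its small RNAs were tailed with poly(A), joined to a tag and stained with Cy3 or Cy5, and a service provider ran the arrays, per the labels' protocols. Each sample has its own spot table of 3968 spots, with 5 spots for each of 599 mature miRNA probes, 669 empty spots and control probes. Per the file headers, its values are the mean intensity of each spot on a linear scale, and the empty spots lie well above 0, so the background had not been subtracted. A second deposited table holds the authors' processed intensity of each of the 599 miRNAs in whole numbers, with medians of 17 to 19 per sample. How those values were normalised is not given in the sources used here, so their scale and centring stay unknown. Across the tested miRNAs, each of its columns correlated best with the scanner intensity of its own sample (Spearman's rho 0.995 to 0.999, against at most 0.965 with another sample), and it served as an alternative only.

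Groups, replicate numbers, dye, sex and age come from the labels, and the series describes the samples as individual mice. The tables were read in R 4.3.3 and analysed with limma 3.58.1. The spot intensity was background-corrected with normexp (offset 50, fitted on all spots of a sample), log2 values were averaged over the 5 spots of a probe, and the 6 samples were quantile-normalised over all 599 probes. Quantile normalisation gives miRNAs of equal rank the same value, so some samples share a level. A miRNA was called above background in a sample where its mean log2 intensity was over the mean of the empty spots by more than 3 SD. The median empty spot read 219 to 459 in the Cy3 samples and 34.4 to 51.2 in the Cy5 samples, and the median tested miRNA lay between 1.37 times (treated replicate 2) and 5.34 times (treated replicate 1) that of its own sample's empty spots. MiRNAs above background in at least 3 of the 6 samples, counted without regard to group, were tested (197), and the other 402 were not. No local background value was used, and the precision is limited by the number of arrays.

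Treated and control samples were compared with limma (lmFit and eBayes, two-sided) in a model with group and dye, since 2 of 3 controls carried Cy3 and 2 of 3 treated samples Cy5. Treated replicate 2 was thus the only treated sample in Cy3, and control replicate 2 the only control in Cy5. When either is left out, its dye holds a single group. The dye-adjusted difference then sets the other of these 2 samples alone against the 2 samples of the other group in its dye. Benjamini-Hochberg adjusted p-values under 0.05 were called, and fold changes, SE and 95% confidence intervals come from the same fit. All p-values named as limma's are from that fit unless another is named. A difference of a miRNA not above background in any sample of one group is given as a lower bound, against the mean of the higher of each sample's lowest detected level and its own level. The 15 miRNA lists were fixed before the data were examined: miRNAs the study is known to have followed up, vascular smooth muscle, kidney-enriched tubule, epithelial miR-200 family, let-7, miR-30 and miR-29 families, the miR-17 to miR-92 and paralogous clusters, endothelial, leukocyte, erythrocyte, fibrosis and injury, angiotensin-linked, the Dlk1-Dio3 imprinted cluster, and other tissues. MiR-21, miR-132, miR-212, miR-155 and miR-410 stand in more than a single list. The 12 lists with at least 3 tested members were tested with limma's camera (preset correlation 0.01, adjusted over the lists), with an estimated correlation and limma's fry as alternatives.

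The named miRNAs follow a rule set before the data were examined: those past the threshold, filled up to 20 with those of smallest unadjusted p, the miRNAs followed up by the study, the brightest members of each list and the 10 brightest miRNAs. Names are those of the array, and 578 of 599 matched a miRNA gene of the GRCm38.p6 table by name. No genome build is named in the sources used here, so no positions are given.

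The labels give each group the replicate numbers 1, 2 and 3 and do not say what a shared number marks. Across the tested miRNAs, the deviations of same-numbered samples from their group means correlated at r = 0.447, 0.460 and 0.781, all over 0.1, so the numbers were taken to pair the samples. Samples of different number gave r between -0.829 and 0.256. Control replicate 1 with treated replicate 2 (0.256) and control replicate 2 with treated replicate 1 (0.246) also lay over 0.1. Deviations within a group of 3 sum to 0, so these correlations are not independent. The threshold of 0.1 alone therefore does not tell pair 1 from pair 2. Across the 669 empty spots, same-numbered samples, which carried opposite dyes, correlated at Spearman's rho of 0.494, 0.529 and 0.356, and samples of opposite dye and different number at -0.0109 to 0.214. Spots and miRNAs are not independent replicates. The pairing thus comes from the data, and fits with the replicate number as a block are alternatives.

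The test was tested on simulated data with the real samples' residual spread, drawn independently for each miRNA and sample. The real samples also held a correlation between same-numbered samples (consensus 0.764) and between members of some lists (0.976 for miR-30). The simulated rates thus describe a simpler setting than these data. Of miRNAs changed 2-fold, 4-fold and 8-fold between treated and control samples, 5.25%, 73.2% and 88.2% passed, with 20 of 197 changed in each of 100 runs. The camera test of the 5 erythrocyte miRNAs gave an unadjusted p under 0.05 in 13% of 100 runs without any shift, more often than its nominal rate, and in 61% and 98% of runs with shifts of 0.5 and 1. The alternatives set before the data were examined were: no dye term, the replicate block with and without the dye term, a sex term, the 3.5-month males only (2 per group), cyclic loess, scaling to the 75th percentile of the miRNAs above background in all samples, no normalisation between samples, quantiles over detected miRNAs, the deposited processed intensity (log2 with a pseudocount of 1), a normexp offset of 10, plain subtraction of the median empty spot with a floor of 16, the median over spots, no detection filter, detection in all 6 samples, a prior with trend, and each sample left out in turn.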

Results

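Small RNA from the renal cortex of 6 C57Bl6 mice was profiled on microarrays with probes for 599 mature mouse miRNAs. The control group held 3 untreated mice. The treated group held 3 mice given a diet of 0.05% sodium together with captopril, an inhibitor of angiotensin converting enzyme, at 0.5 g/L in the drinking water for 10 days. Each group held 2 males and 1 female, and all mice were 3.5 months old except treated replicate 1, a female of 5 months. Control replicates 1 and 3 and treated replicate 2 carried Cy3, and the other 3 samples carried Cy5. Between 127 (control replicate 2) and 229 (treated replicate 1) miRNAs lay above background in a sample, 117 did so in all 6 samples and 354 in none. The 197 miRNAs above background in at least 3 of the 6 samples were tested. The small number of samples limited the precision.

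The 10 miRNAs with the brightest probes are given with the level of each group, and the brightness of different probes does not rank the abundance of their miRNAs. Let-7a had a log2 normalised intensity of 15.36 ± 0.16 in control (SD, n = 3) and 15.45 in each treated sample, the top value that quantile normalisation sets. Let-7f lay at 15.27 ± 0.17 in control and 15.33 ± 0.06 in treated samples, let-7c at 15.02 ± 0.26 and 15.23 ± 0.04, let-7d at 14.88 ± 0.51 and 15.14 ± 0.06, let-7b at 14.68 ± 0.53 and 15.01 ± 0.10, and let-7g at 14.12 ± 0.22 and 14.19 ± 0.10. MiR-709 (15.13 ± 0.21 in control, 15.05 ± 0.27 in treated), miR-26a (14.92 ± 0.47 and 14.68 ± 0.10), miR-30c (14.29 ± 0.93 and 14.02 ± 0.17) and miR-21 (13.86 ± 0.49 and 14.38 ± 0.16) made up the 10. The let-7 members differ by few bases, so part of each probe's signal can come from its relatives.

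The comparison of treated with control mice asks which miRNAs of the cortex differ under sodium restriction with captopril, a regimen known to raise renin expression and the number of renin-producing cells. In limma with a dye term, no miRNA passed an adjusted p of 0.05 in either direction. That fit has no term for the replicate number, and same-numbered samples correlated (consensus 0.764), so it is too cautious if they are pairs. An unadjusted p under 0.05 was reached by 1 of 197 miRNAs, fewer than that threshold gives on average without any effect. That miRNA was miR-327, which lay 0.77 higher in treated mice on the log2 scale (95% interval 0.09 to 1.45, adjusted p = 0.995) and higher in all 3 pairs of same-numbered samples, but near background, at 6.65 ± 0.03 in control and 7.57 ± 0.51 in treated samples, and detected in 3 of 6. Over the alternatives its difference ran from 0.098 under 75th percentile scaling to 1.84 with plain background subtraction. Among miRNAs well above background, the red cell miRNA miR-451 lay 0.80 higher (95% interval -0.14 to 1.74), miR-218, which is encoded within the Slit2 and Slit3 genes, 0.81 higher (-0.23 to 1.84), and miR-192, an abundant miRNA of the renal tubule, differed by -0.46 (-1.15 to 0.23), from 13.19 ± 0.34 in control to 12.67 ± 0.18 in treated samples (SD, n = 3 each). The adjusted p of each was 0.995 in limma, and over the alternatives the difference ran from 0.50 to 1.45 for miR-451, from 0.28 to 1.39 for miR-218 and from -0.77 to 0.29 for miR-192.

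The other miRNAs among the 20 of smallest unadjusted p lay on both sides of 0. Higher in treated samples in all 3 pairs were miR-15a (0.72), miR-374 (0.72), miR-486 (0.89), miR-744 (0.31), miR-21 (0.41) and miR-125b-5p. Lower in all 3 pairs were miR-107 (-0.54) and its near-identical relative miR-103 (-0.42), miR-106a (-0.36), miR-199a-3p (-0.40), miR-322* (-0.29), miR-191 (-0.35) and miR-214 (-0.36). The pairs disagreed for miR-182 (-0.52), miR-1224 (-0.54) and miR-377 (-2.02, SE 1.02), whose level in control replicate 2, 11.70, set it apart from the 2 other controls, at 6.41 and 6.36. The difference of miR-377 was -0.89 without a dye term and ran over the alternatives from -3.97 without treated replicate 2 to -0.066 without control replicate 2, that of miR-182 was -0.25 without a dye term and ran from -1.02 to -0.022 without the same samples, and that of miR-1224 ran from -0.97 to 0.039. Without treated replicate 2 the dye-adjusted difference rests on control replicate 2 alone for the controls. Without control replicate 2 it rests on treated replicate 2 alone for the treated group. Of the 197 miRNAs, 28 were higher and 32 lower in all 3 pairs, and agreement of only 3 pairs arises often without any effect. The 20 miRNAs were picked by p in these same samples, so agreement between their pairs is not separate support. These differences are relative to the bulk of miRNAs: without normalisation between samples the median of all 197 moved to 0.29, and miR-107, miR-103, miR-192, miR-199a-3p, miR-322*, miR-191, miR-214 and miR-1224 then lay above 0, while scaling to the 75th percentile moved the median to -0.53 and put miR-744 below 0.

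**Figure D1:**
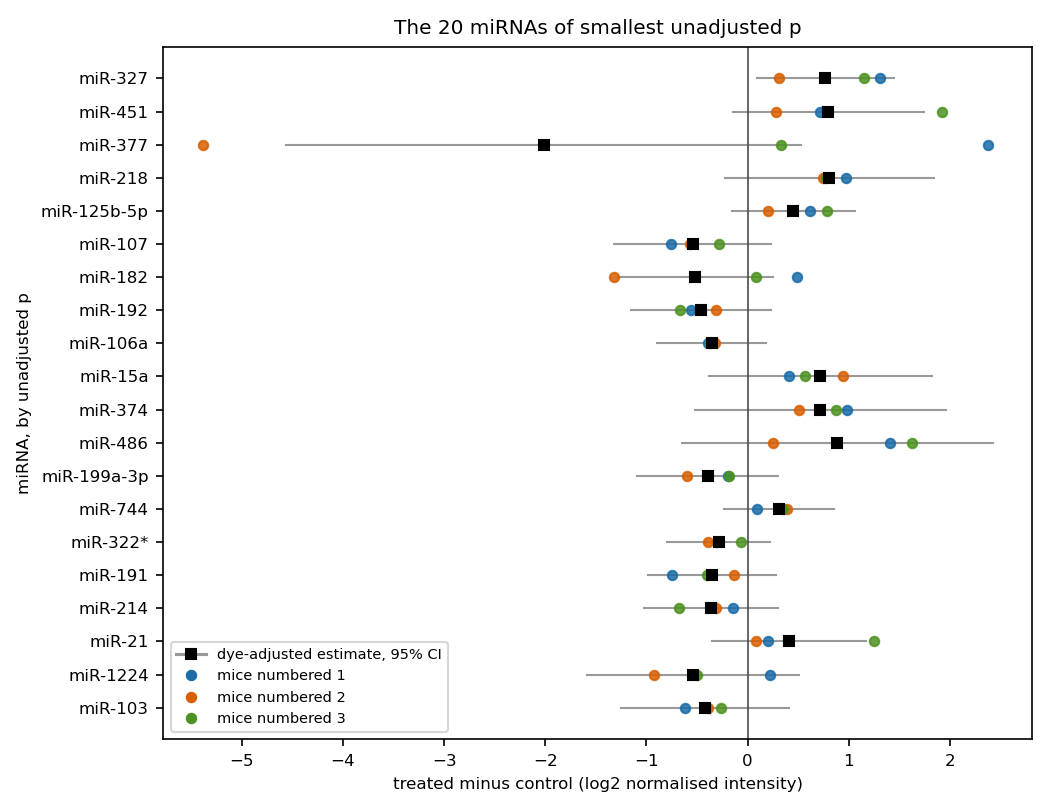
The 20 miRNAs of smallest unadjusted p, each with the treated minus control difference in log2 normalised intensity from limma with a dye term (black squares, grey bars are 95% confidence intervals) and the plain difference within each pair of same-numbered mice (coloured points, 1 mouse per group in each pair). Only the interval of miR-327, from 0.09 to 1.45, excludes 0, and the 3 pairs of miR-377 spread from -5.39 to 2.38.

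The 95% interval of the treated minus control difference lay within 2-fold either way for 104 of the 197 miRNAs and within 4-fold for 182, with a median SE of 0.31 on the log2 scale. With the replicate number as a block beside the dye, 15 miRNAs had an unadjusted p under 0.05 in limma, 10 higher and 5 lower, the smallest adjusted p was 0.287, and 171 intervals lay within 2-fold. That fit left 1 residual degree of freedom per miRNA, against 3.97 of limma's prior. Its SE, p-values and intervals thus lean on the spread pooled over miRNAs. The 5 lower included miR-377 and miR-182, whose pairs disagreed in sign. The count of 1 became 12 without treated replicate 2, 12 without control replicate 2, 0 without treated replicate 1 and 0 without treated replicate 3, 2 without control replicate 3, and 4 when both samples numbered 3, the pair that stood apart from the rest, were left out. Without treated replicate 2 or without control replicate 2, 1 mouse stands for its group with the dye term. Those 2 counts thus describe that mouse as much as the treatment. The fit of all 6 samples averages the differences of these 2 fits. Each of the 2 mice therefore carries as much weight in it as the 2 others of its group together.

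MiR-330 and miR-125b-5p are miRNAs that the study is known to have followed up in juxtaglomerular cells, the renin-producing cells of the afferent arteriole, so their place on these arrays is not independent evidence. MiR-125b-5p was well above background in all 6 samples, at 11.95 ± 0.14 in control and 12.49 ± 0.30 in treated samples (SD, n = 3 each). It lay 0.45 higher in treated mice (SE 0.24, 95% interval -0.15 to 1.06) and higher in 3 of 3 pairs, with an adjusted p = 0.995 in limma, and its difference ran from 0.30 to 1.12 over the alternatives. MiR-330 did not rise above background in any sample. Its star strand, miR-330*, was above background in 3 of 6 samples, at 6.57 ± 0.13 in control and 6.56 ± 0.15 in treated samples, a difference of -0.02 (SE 0.23). Neither of the 2 tested miRNAs passed when adjusted over the list alone, where the smaller adjusted p was 0.231.

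The erythrocyte list ranked above the other tested miRNAs in its treated minus control differences (median difference 0.72, adjusted p = 0.00134 in limma's camera with a preset correlation of 0.01). The call did not hold with an estimated correlation between the members, where the list's adjusted p = 0.332, or 0.836 with the replicate number as a block, or in limma's fry (adjusted p = 0.350), so a rise of the list in treated cortex was not established. Without the block, the correlation estimated between the members was -0.171, so members that vary together do not account for the loss there. With an estimated correlation, camera refers its statistic to the residual degrees of freedom of the fit, 3 without the block and 1 with it. At the preset correlation it uses many more, set by the number of miRNAs. Fewer degrees of freedom raise p by themselves, so the loss does not show that the members vary together. The unadjusted p was 0.0277 in camera with that correlation and 0.0292 in fry. The 5 tested members of this list were miR-451 and miR-486, which are abundant in erythroid cells, and miR-15a, miR-15b and miR-16, which most tissues, kidney included, also express. All 5 differences lay above 0, and 4 of the miRNAs were higher in all 3 pairs. Each difference averages 1 contrast within Cy3 and 1 within Cy5, and these differed in sign for all members but miR-451. They were -0.27 and 2.04 for miR-486, -0.089 and 1.53 for miR-15a, and -0.69 and 1.76 for miR-15b. For miR-16 the lower was -0.039. MiR-451 lay at 9.52 ± 0.70 in control and 10.49 ± 0.25 in treated samples, miR-486 at 8.28 ± 1.13 and 9.37 ± 0.46, miR-15a at 10.32 ± 0.63 and 10.97 ± 0.44, miR-15b at 11.16 ± 1.50 and 11.86 ± 0.64 (difference 0.53), and miR-16 at 13.09 ± 0.48 and 13.40 ± 0.41 (difference 0.32). The sixth member, miR-144, was not above background in any sample. Of the 12 lists tested in camera, no other passed. No member passed by itself, over all miRNAs tested or when adjusted over the list alone (smallest adjusted p 0.339). Within pairs, the median of the 5 differences was 0.45, 0.28 and 1.62 in pairs 1, 2 and 3. The call was lost in camera without treated replicate 2 (adjusted p = 0.478) and without control replicate 2 (adjusted p = 0.146). With the dye term, these 2 fits set control replicate 2 alone, or treated replicate 2 alone, against 2 samples of the other group. The list's adjusted p was 0.0379 without control replicate 3, where the list's median differed by -1.55 from the other samples, and it ran from 3.50e-07 to 0.836 over the alternatives tried. In simulated samples without any shift of these 5 miRNAs, and with independent miRNAs and unpaired samples, camera gave the list an unadjusted p under 0.05 in 13% of runs.

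**Figure D2:**
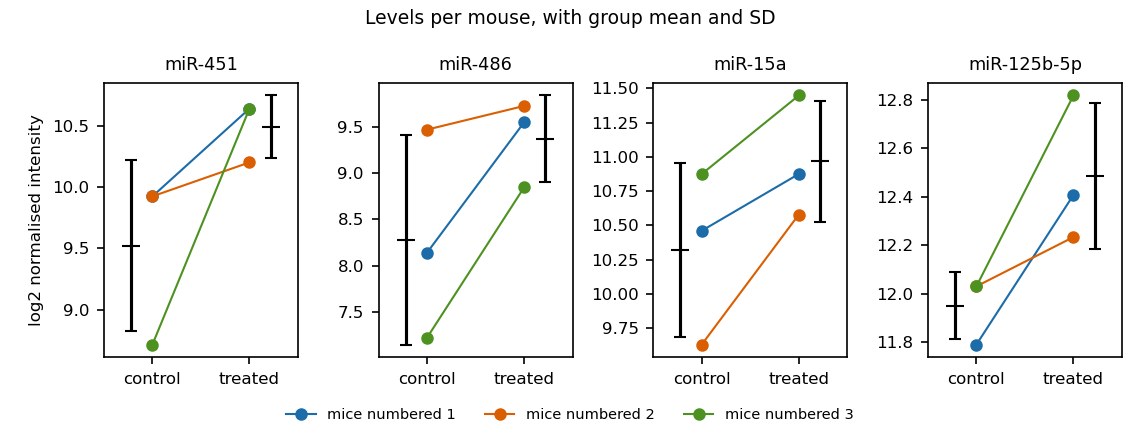
Log2 normalised intensity of miR-451, miR-486, miR-15a and miR-125b-5p in each mouse, with lines joining same-numbered control and treated mice and black bars for the mean ± SD of each group (n = 3). Each of the 4 miRNAs was higher in the treated mouse of all 3 pairs, and for miR-451 and miR-486 the lowest control, control replicate 3, lay at 8.72 and 7.22.

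Lists of renal and vascular cell types did not pass the test, and the camera direction of the tubule, miR-200 and smooth muscle lists turned when a sample was left out. Of the kidney-enriched tubule miRNAs, 8 were tested and none passed, with a median difference of 0.05 and an adjusted p of 0.983 in camera, whose direction was down, against the sign of the median, and turned to up under 75th percentile scaling and with the deposited processed values. Their brightest members were miR-10b, at 13.60 ± 0.39 in control and 13.83 ± 0.17 in treated samples, and miR-10a, at 12.91 ± 1.05 and 13.48 ± 0.32. The 5 miRNAs of the epithelial miR-200 family had a median difference of -0.01, a mean of 0.03 and an adjusted p of 0.983 with the direction down, which turned to up with cyclic loess and under 75th percentile scaling. MiR-200b lay at 13.00 ± 0.52 in control and 13.29 ± 0.10 in treated samples, and miR-200c at 11.57 ± 0.96 and 12.003 ± 0.42. In the vascular smooth muscle list, 6 miRNAs were tested and none passed (median -0.09, adjusted p = 0.648, direction down but up under 75th percentile scaling). Its brightest members, miR-145 and miR-143, lay at 11.17 ± 0.36 and 11.25 ± 0.76 in control and at 11.35 ± 0.09 and 11.19 ± 0.48 in treated samples. The endothelial miR-126-3p lay at 13.96 ± 0.21 and 13.92 ± 0.14, and miR-126-5p at 7.13 ± 0.80 and 7.05 ± 0.59, in control and treated samples, and neither passed.

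Lists tied to angiotensin signalling, injury and leukocytes did not pass either, and their directions too turned when a sample was left out. The angiotensin-linked list turned only without treated replicate 2, where control replicate 2 alone stands for the controls. The injury list turned only without control replicate 2, where treated replicate 2 alone stands for the treated group. The angiotensin-linked list had 7 tested members, a median difference of 0.02 and an adjusted p of 0.527. The fibrosis and injury list had 7, a median of -0.08 and an adjusted p of 0.541, and 3 of its members were lower in all 3 pairs. MiR-21, which is induced in injured kidney and stands in both lists, was 0.41 higher in treated mice (95% interval -0.35 to 1.17), whereas the fibroblast miRNAs miR-199a-3p and miR-214 differed by -0.40 and -0.36. MiR-24, of the angiotensin-linked list, lay at 11.92 ± 0.80 in control and 11.69 ± 0.35 in treated samples. The 4 tested leukocyte miRNAs had a median of -0.02, a mean of 0.07 and an adjusted p of 0.983, with the direction up. Among them miR-150 lay at 9.01 ± 0.70 in control and 9.54 ± 0.56 in treated samples, and miR-146a at 9.82 ± 0.48 and 9.80 ± 0.13.

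Of the miRNA families and clusters, none passed with quantile normalisation of all 6 samples, and the direction of each turned when a sample was left out. For the miR-17 to miR-92 clusters this was only without treated replicate 2, and for the miR-29 family only without control replicate 2. In these fits the dye-adjusted difference rests on 1 sample of a group. The 9 let-7 miRNAs had a median difference of 0.20 and an adjusted p of 0.361, with the direction up. That direction turned with cyclic loess normalisation, where the list passed as down (adjusted p = 0.0212), and the list passed as up without control replicate 1 (adjusted p = 0.0212). Both calls were made at the preset correlation of 0.01, and the correlation was not estimated in those 2 fits. In the quantile-normalised 6 samples the correlation estimated between the members was 0.914. With it the adjusted p of the list in camera was 0.984. Over its alternatives the adjusted p ran from 0.0212 to 0.992. The 5 miR-30 miRNAs had a median of -0.17 and an adjusted p of 0.527, with the direction turned under 75th percentile scaling. MiR-30b lay at 13.86 ± 0.92 in control and 13.63 ± 0.29 in treated samples. The 3 miR-29 miRNAs had a median of 0.41 and an adjusted p of 0.648, and passed as up without treated replicate 2 (adjusted p = 0.0384, with 0.0384 to 0.988 over the alternatives), again at the preset correlation, whereas the estimated correlation was 0.899 and gave an adjusted p of 0.984 with all 6 samples. In the fit that passed, control replicate 2 alone stood for the controls, and the correlation was not estimated. MiR-29a lay at 13.34 ± 1.07 in control and 13.05 ± 0.30 in treated samples, and miR-29c at 11.56 ± 1.57 and 11.66 ± 0.40. Of the miR-17 to miR-92 and paralogous clusters, 10 miRNAs were tested, with a median of -0.18 and an adjusted p of 0.527, and 5 were lower in all 3 pairs. MiR-92a lay at 10.49 ± 0.50 in control and 10.89 ± 0.16 in treated samples, and miR-25 at 9.67 ± 0.46 and 9.78 ± 0.30.

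Of 36 miRNAs of the imprinted Dlk1-Dio3 cluster on the array, 2 were tested, miR-377 and miR-329, the latter at 6.69 ± 0.04 in control and 6.55 ± 0.02 in treated samples. Markers of liver, brain and striated muscle gave 3 tested miRNAs with a median of 0.23 and an adjusted p of 0.497, turned to down under 75th percentile scaling. Their brightest member, miR-128, lay at 7.76 ± 0.28 in control and 7.82 ± 0.17 in treated samples. The liver miRNA miR-122 was the only miRNA above background in all 3 samples of one group and in none of the other. Its mean in treated samples lay 1.07-fold above the bound set for the control samples, which does not count the spread over samples. The measured means were 6.94 in treated and 6.68 in control samples. Its dye-adjusted difference was 0.30 (SE 0.31, adjusted p = 0.995 in limma), and it lay at -0.46 under 75th percentile scaling.

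**Figure D3:**
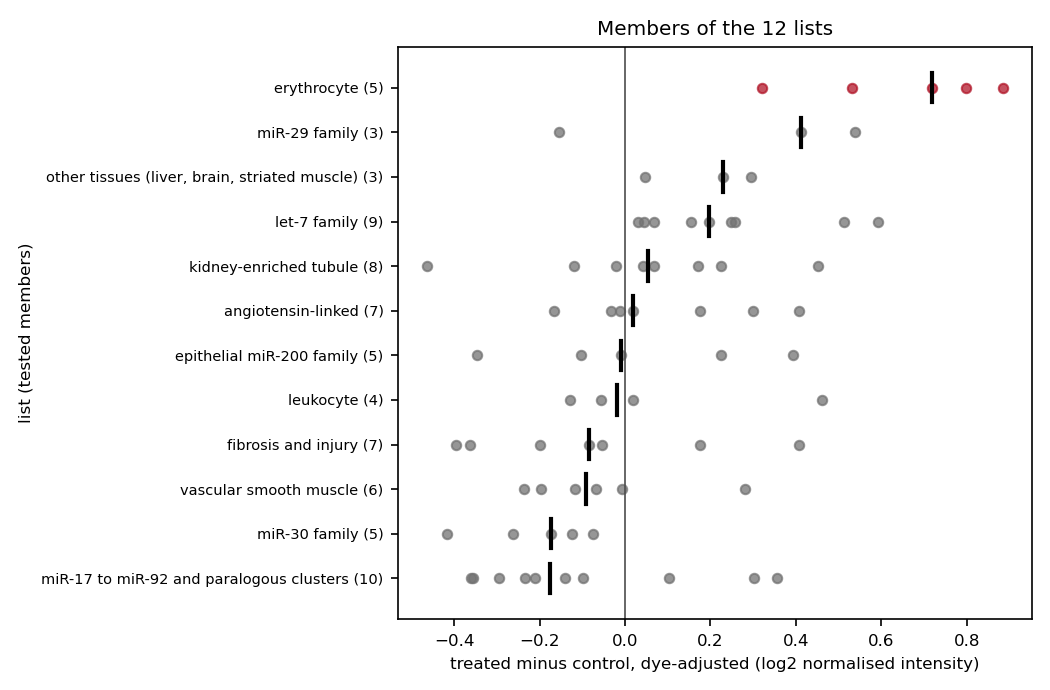
Treated minus control difference in log2 normalised intensity, from limma with a dye term, of each tested member (points) of the 12 lists with at least 3 tested miRNAs, with each list's median as a black bar and the number of members in brackets. The red points, the erythrocyte list with its median of 0.72, mark the list with an adjusted camera p under 0.05; the let-7 list, with a median of 0.20 here, turned direction with cyclic loess, and the miR-30, tubule, miR-200, smooth muscle and other-tissue lists did so under 75th percentile scaling.

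The samples numbered 3 differed from the others in more than their group. The first principal component of the 197 miRNAs held 65.9% of the variance and placed control replicate 3 at 10.6 and treated replicate 3 at 3.07, with the other 4 samples between -5.61 and -1.68. Control replicate 3 and treated replicate 1 were the 2 females, and a sex term beside the dye gave 0 miRNAs at an adjusted p under 0.05 and 0 at an unadjusted p under 0.05 in limma. For the dye term the counts were 0 and 4.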

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

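The count of miRNAs at an adjusted p under 0.05 was 0 in each direction in limma under all 26 alternatives, with the smallest adjusted p, 0.175, under a random block. The alternatives chosen after seeing the data were the random block on the replicate number, leaving out both samples numbered 3, normexp fitted on the empty spots, same-numbered samples taken as a two-colour array with loess and the replicate block, the erythrocyte list reduced to miR-451 and miR-486, and camera with the replicate block and an estimated correlation. What signal over background limits is the dim end: 402 of 599 miRNAs were not tested, and the median tested miRNA of treated replicate 2 lay 1.37 times above its empty spots. Among miRNAs named by level alone, miR-126-5p, miR-128 and miR-329, all dim, moved by more than the SD over the samples under 3, 3 and 4 alternatives. Where a result changed, the cause was not tested, except that detection in all 6 samples tests fewer miRNAs, 117, and no detection filter tests more, 599. Leaving out treated or control replicate 2 also changes what is compared, since with the dye term 1 sample then stands for its group.

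The count at an unadjusted p under 0.05, which was 1, became 15 with the replicate block and the dye term, a fit with 1 residual degree of freedom, and 19 with the replicate block without the dye term. It became 20 with the random block (consensus correlation 0.764) and 9 with two-colour loess and the replicate block. The replicate block changed no other call: the erythrocyte list passed with it (adjusted p = 1.18e-04 in camera, 0.836 with an estimated correlation), and the other 11 lists did not. It became 3 without a dye term, 0 with a sex term, 2 with cyclic loess, 2 with the median over spots, 8 without a detection filter, 0 with detection in all 6 samples and 4 without both samples numbered 3. With each sample left out in turn it ran from 0 to 12.

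The erythrocyte list kept its direction in all 18 alternatives and passed in 12 of the 17 that tested the full list, with adjusted p-values from 3.50e-07 (75th percentile scaling) to 0.836. It did not pass with an estimated correlation, without (0.332) or with (0.836) the replicate block, or in fry (0.350), and with each sample left out its adjusted p ran from 9.76e-04 to 0.478. It passed without both samples numbered 3 (0.0143). Reduced to miR-451 and miR-486, its largest differences and fewer members than the minimum of 3, it had an unadjusted p of 0.00144 at the preset correlation, which adds no support.

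Named miRNAs whose difference turned sign did so without passing the test in either direction. In the 3.5-month males, miR-330* lay at 0.069 and miR-15b at -0.27. Under 75th percentile scaling, miR-744 lay at -0.33 and miR-122 at -0.46. Without normalisation between samples, miR-107 lay at 0.15, miR-192 at 0.29, miR-199a-3p at 0.26, miR-322* at 0.071, miR-191 at 0.31, miR-214 at 0.31, miR-1224 at 0.039 and miR-103 at 0.15. MiR-330* lay at 0.16 with the deposited processed values and at 0.078 with plain background subtraction. With each sample left out in turn, the difference ran from -0.089 to 1.53 for miR-15a, -0.27 to 2.04 for miR-486, -0.84 to 0.046 for miR-199a-3p, -0.20 to 0.15 for miR-330*, -0.22 to 0.81 for miR-122, -0.039 to 0.68 for miR-16 and -0.69 to 1.76 for miR-15b. Over all alternatives, other differences among the 20 miRNAs of smallest unadjusted p ran from 0.18 to 1.21 for miR-374, -0.33 to 0.59 for miR-744, 0.15 to 1.05 for miR-21, -0.72 to 0.15 for miR-107, -0.67 to 0.15 for miR-103, -0.89 to -0.070 for miR-106a, -0.75 to 0.071 for miR-322*, -0.67 to 0.31 for miR-191 and -0.70 to 0.31 for miR-214.

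Lists other than the erythrocyte list turned direction as follows, with the adjusted p after the turn. The tubule list turned without a dye term (0.904), with the replicate block (0.875), with the block and an estimated correlation (0.897), under 75th percentile scaling (0.396), with the deposited values (0.992), in fry (0.988), with normexp on the empty spots (0.989) and with two-colour loess (0.751). The miR-200 list turned without a dye term (0.946), with cyclic loess (0.888), under 75th percentile scaling (0.473) and in fry (0.988). The let-7 list turned with cyclic loess (0.0212), two-colour loess (0.402) and without both samples numbered 3 (0.911), the miR-29 list without a dye term (0.904), and the other-tissue list under 75th percentile scaling (0.879). The smooth muscle and miR-30 lists turned under 75th percentile scaling (0.879 and 0.227) and without both samples numbered 3 (0.685 and 0.663), and the leukocyte list without both samples numbered 3 (0.694). Leaving out a single sample turned lists as well. Without treated replicate 2 or without control replicate 2, the dye-adjusted difference rests on 1 sample of a group. Without control replicate 1 the tubule and miR-200 lists turned to up, and let-7 passed as up, its own direction, at the preset correlation. Without control replicate 2 the tubule and fibrosis lists turned to up and miR-29 to down. Without control replicate 3 the smooth muscle and miR-30 lists turned to up and let-7 and leukocyte to down. Without treated replicate 1 miR-200 turned to up and leukocyte to down, and without treated replicate 3 the tubule list turned to up. Without treated replicate 2 the smooth muscle, miR-200, miR-30 and miR-17 to miR-92 lists turned to up and the let-7, leukocyte and angiotensin-linked lists to down, and miR-29 passed as up, its own direction, at the preset correlation. With each sample left out in turn, adjusted p-values ran from 0.248 to 0.816 for smooth muscle, 0.167 to 0.877 for tubule, 0.744 to 0.974 for miR-200, 0.0212 to 0.791 for let-7, 0.123 to 0.478 for miR-30, 0.217 to 0.974 for the miR-17 to miR-92 clusters, 0.167 to 0.816 for leukocyte, 0.387 to 0.816 for fibrosis and injury, 0.0384 to 0.968 for miR-29 and 0.325 to 0.892 for angiotensin-linked miRNAs.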

Other observations

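Control replicate 3 had a miRNA profile of its own, described here with miRNAs chosen after their values were seen. All 9 let-7 miRNAs lay lower in it than in the mean of the other 5 samples, by a median of -0.87 on the log2 scale, led by miR-98 (9.01 against 13.01 ± 1.17, SD over the other 5) and let-7e (11.68 against 14.43 ± 0.50). All 5 miR-30 miRNAs lay higher, by a median of 1.45, led by miR-30e (13.39 against 10.61 ± 0.58), and so did all 3 miR-29 miRNAs (median 1.64) and all 6 of the smooth muscle list (median 0.72). MiR-196a (8.78 against 11.67 ± 0.91), miR-15b (9.47 against 11.92 ± 0.51) and miR-155 (6.87 against 9.26 ± 0.87) were low, and miR-101a (10.29 against 7.81 ± 1.03) and miR-690 (12.88 against 10.44 ± 0.57) high. Treated replicate 3 lay between control replicate 3 and the mean of the other 5 samples for miR-98 (10.97), let-7e (13.55) and miR-30e (11.20).

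The tests of dye, blood, sex, near-identical probes and shared conditions in the next paragraphs were chosen after the results were seen, and the counts of other splits of the samples were planned. The erythrocyte list lay higher in treated samples. The dye stays open: treated minus control of the list's mean per sample was 0.744 (SE 0.254) without the dye in the model and 0.651 with it (SE 0.266, 95% interval -0.20 to 1.50), and only control and treated replicate 2 broke the match of dye and group. Blood left in the tissue, a candidate source, and a rise of these miRNAs in treated kidney cannot be told apart: miR-451 and miR-486 differed by 0.318 more than miR-15a, miR-15b and miR-16 in the fit with dye (SE 0.464; plain mean of the 3 pairs 0.481, SE 0.337), and the leukocyte miRNAs differed by 0.07 in the mean (SD over members 0.27). Of the 9 splits of the 6 samples that could be fitted with the dye, 1, the real one, gave the list a p as small (1.12e-04, against 0.00174 as the smallest of the others), and 9 splits are too few for a share under 0.05.

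Control replicate 3 stood apart from the other samples, with an SD of its differences from them of 0.92, against 0.40 to 0.64 for each other sample. The other female, treated replicate 1, did not share its place on the first principal component (-2.85 against 10.6), and the deviations of control replicate 3 from its group correlated at r = -0.452 with those of that female and at r = -0.520 with those of the male treated replicate 2 (difference 0.0677, bootstrap SE 0.121), but with 1 female in each group, the treated one also older, sex stays open. The deviations of control replicate 3 correlated at r = 0.781 (SE 0.0279) with those of treated replicate 3. Conditions shared by the samples numbered 3 may thus account for part of the profile. The same r was used to take the numbers as pairs, so it is no separate test of shared conditions. Deviations within a group of 3 also sum to 0, so these correlations are not independent. Each SE in this paragraph is taken over miRNAs as if they were independent, and measures no spread over mice. A control probe read 26.4 and 17.65 times the empty spots in the control and treated samples numbered 3, and 1.20 to 2.89 times in the other 4. Cross-reading of near-identical miRNAs stays open: 49 probes with a brighter miRNA within 4 edits differed from the other 148 by 0.119 in the median (bootstrap SE 0.148). The signal of a mismatched control probe, as a share of its perfectly matched form, differed between samples. It was 2.67% and 0.66% in the control and treated samples numbered 3, and 3.51% to 16.1% in the other 4.

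The number of miRNAs at an unadjusted p under 0.05 in limma, 1 for treated against control, was reached in 8 of the 9 splits that could be fitted with the dye. Most of these keep same-numbered samples on one side, unlike the real split. Of the others that part every pair, control replicate 1 with treated replicates 2 and 3 gave 0. Control replicates 1 and 2 with treated replicate 3 gave 1. The highest count, 46, came from control replicates 1 and 2 with treated replicate 2 against the other 3 samples, a structure of the samples that does not follow treatment. With the replicate block and no dye term, the real split gave 19 miRNAs, and 1 of the 4 splits that part every pair, the real one, gave as many. The highest of the others, 9, was the split by dye, and with the dye term beside the block the real count was 15, below the 25 of the split of control replicate 1 with treated replicates 2 and 3 against the other samples. Neither 9 nor 4 splits allow a share under 0.05.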
